A study of Mus musculus with 8 samples.

How the data were processed

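Mouse primary T cells were kept in culture as control cells or treated with an agent that the labels call PTC and do not describe further, for 24 h. Total RNA was taken with Trizol. In each condition 2 samples were immunoprecipitated for N6-methyladenosine (m6A), a methylated form of adenosine in RNA, and 2 samples were sequenced as input, which gives 8 samples in 4 groups of 2. Groups and sample numbers were taken from the sample titles. The labels do not say whether the samples came from separate animals or cultures.

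The deposited tables used here are 2 peak lists, 1 for the control condition and 1 for the PTC condition, and a summary table with 1 row per condition. No table used here holds values per sample. Per the submitters' processing notes, the tools were BWA 0.7.12 and MACS2 2.1.0 and the genome build was GRCm39, with no role or settings given. The layout of the lists, with exon blocks, a gene identifier and a strand for each peak, is not that of a MACS2 list, and the caller and its threshold are not given in the sources used here. Whether the authors pooled the 2 samples of a group before calling peaks is not given either. The highest false discovery rate (FDR) in the lists was 4.27% for control and 4.68% for PTC.

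Per the file headers, each peak carries a fold enrichment, a p-value and an FDR, all of them the authors' own values. The deposited fold enrichment is a linear ratio, taken here as immunoprecipitate over input, and its scaling is not stated. The deposited p-value equals the deposited log p to within 0.02 on a log10 scale, so the log columns are log10. The FDR was used as −log10 FDR, and an FDR too small for the list to hold (41 control and 80 PTC peaks) was ranked above every other. Fold and FDR were used to describe, rank and filter peaks within a list and not to compare a peak between lists. The authors' deposited table of summary values gives the fragment length, the number of peaks and the percent of reads in peaks for each condition. Read depth per sample is unknown, since no counts are given.

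Peak coordinates were compared with GENCODE mouse release M21, which is on GRCm38. Of the control peaks 99.9% lay inside the gene with the same Ensembl identifier in that annotation, and of the PTC peaks 99.8%. The coordinates are therefore read as GRCm38, although the processing notes name GRCm39, and none was converted. Positions are given from 1. Gene symbols are those of GENCODE M21, or those of the lists, where given, for genes that it does not hold. Symbols of the gene lists were matched to Ensembl identifiers, of which 663 were found and 1 symbol was not.

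Peaks of the lists were compared over their exon blocks on the same strand with bedtools 2.31.1, and a peak counted as overlapped when at least 1 bp was shared with a peak of the other list. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only and not the spread between samples. The overlap was set beside that of 100 random placements of the other list's peaks along the joined exons of their own genes. A gene was assigned to the control list only, the PTC list only or both lists by the presence of any peak. As the lists give no summit, the midpoint of the exon blocks stood for the peak. A region named for a single peak is that of its midpoint, and the peak can reach into other regions. Midpoints in protein-coding genes were assigned to coding sequence, then 3' UTR, then 5' UTR, then noncoding exon or intron, and to the neighbourhood of a stop codon when within 200 nt along the joined exons. The m6A consensus DRACH (D is A, G or T, R is A or G, H is A, C or T) and its form GGACT were searched in windows of 101 nt of the transcript. Random positions in the exons of the same genes gave the comparison for regions and motifs.

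For each of 22 gene lists written before the data were examined, the share of members in 1 peak list only was placed among 10000 random gene lists of the same size, matched on each gene's highest −log10 FDR in 10 bins. The percentile describes these peak lists and is no p-value. Genes named in the text follow a rule fixed before the data were examined: Bmi1 and the m6A machinery, the 12 genes with the highest −log10 FDR in each list only (without unnamed gene models, mitochondrial genes and pseudogenes), the 6 highest of each list among genes in both, and up to 4 members per gene list and class. Other named genes are said to be chosen after their values were seen. Some genes that the rule names, and 1 gene group counted among those chosen later, are not reported here. With 1 list per condition no test between conditions was possible, no p-value was computed, and presence in 1 list only has no replicate check. A count test between immunoprecipitate and input had been planned for the case of counts per sample and was not run.

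The functions were tested on simulated data. In a control and a PTC list simulated over 7580 genes with 1 peak each, the 4495 peaks copied between the lists were the 4495 called overlapped. Between independent simulated lists of 23361 peaks 42.3% overlapped, against 42.4% by random placement. Of 200 random gene lists drawn from 10854 genes, 5.00% fell outside the central 95% range, and 40 of 40 lists planted with most members in 1 list only lay above it. Smaller effects were not planted. Alternatives covered the overlap rule, stricter thresholds (−log10 FDR of at least 5, fold enrichment of at least 4), equal list length, merging of peaks, gene assignment, region order, motif and window, and the matching of random lists. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.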

Results

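N6-methyladenosine was mapped by immunoprecipitation of methylated RNA and sequencing in mouse primary T cells kept as controls or treated with PTC for 24 h. The series title names BMI1, a Polycomb protein, and immunotherapy of liver cancer, and the comparison asks which transcripts carried m6A peaks in control and in PTC-treated cells. Each condition had 2 immunoprecipitated and 2 input samples, deposited as 1 peak list per condition. The control list held 29586 peaks in 11390 genes and the PTC list 23368 peaks in 10859 genes. The authors' deposited table of summary values counts 19420 control and 15855 PTC peaks, with 36.07% and 33.03% of reads in peaks. Those counts are lower than the lines of the lists by 1.52 and 1.47 times, and the filter behind them is not stated. Because samples were not listed separately, differences between the lists below have no replicate check.

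The strongest peaks of both lists included transcripts typical of lymphocytes. Ccr7, the chemokine receptor of naive T cells, held 1 peak in each list (chromosome 11, 99144286 to 99149053 in the control list), and B2m, the light chain of class I major histocompatibility molecules, and Btg1, an antiproliferative factor, also had control peaks with an FDR too small to be listed. Arf6 and the B cell receptor chain Cd79b were also among the 6 strongest control genes shared by both lists. In the PTC list the 6 were AI662270, AW112010, Arf6, Atp1b3, B2m and BC005537, with ties broken by name. Peaks had a median width of 268 nt in the control list and 270 nt in the PTC list, a median fold enrichment of 3.65 and 3.66 as the authors give it, and a median −log10 FDR of 5.47 and 6.61. Genes carried on average 2.60 control and 2.15 PTC peaks, up to 22 and 21. A −log10 FDR of at least 5 was reached by 15805 control and 13982 PTC peaks, and a fold enrichment of at least 4 by 13327 and 10556.

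Bmi1 held 1 peak in each list, both with a midpoint in the 3' UTR on the plus strand of chromosome 2 and overlapping each other. How far these peaks reach into coding sequence was not computed. The control peak ran from 18684035 to 18686300 with a fold enrichment of 5.84 and a −log10 FDR of 120. The PTC peak ran from 18684065 to 18686599, with 5.31 and 175. The control peak contained 36 DRACH sites and 3 GGACT sites, with the A of GGACT at positions 18684226 (AGAGGGATGGACTGACGAATG), 18684483 (TCTGGTTAGGACTGTTAAGGA) and 18684620 (TAAATGATGGACTAGATGTGA). The PTC peak contained these 3 and a further site at 18686446 (TCTATGATGGACTTACTTCTG). Of the Polycomb genes, which encode histone H2A and H3 modifying complexes, 30 of 33 had a peak and 28 had peaks in both lists, among them Asxl1 and Phc3. Eed, a subunit of Polycomb repressive complex 2, was listed in control only (2 peaks, highest −log10 FDR 6.18), and Rybp in PTC only (1 peak, 2.86). Of 28 Polycomb genes listed at a fold enrichment of at least 4, 17 were in both lists, 6 in control only and 5 in PTC only, and of 28 at a −log10 FDR of at least 5 in both lists 22, 2 and 4.

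Of 24 writer, eraser and reader genes 22 had a peak, 21 of them in both lists. The reader Ythdf2 held 4 control and 2 PTC peaks, and its strongest peaks (chromosome 4, 132186137 to 132210777 and 132186107 to 132205681) had a −log10 FDR of 170 and 242. The methyltransferase gene Mettl3 held 6 control and 4 PTC peaks, the strongest with a midpoint in coding sequence of chromosome 14 (52299754 to 52300052, −log10 FDR 11.8 in the control list and 11.5 in the PTC list). The demethylase genes Fto and Alkbh5 held 5 and 7 control peaks and 2 and 5 PTC peaks. Igf2bp3 was listed in control only, with 1 weak peak (−log10 FDR 3.11), and the single peaks of Ythdc2 in the 2 lists did not overlap. With peaks of a fold enrichment of at least 4 alone, 11 of 20 listed genes were in both lists, 8 in control only and 1 in PTC only (45.0% in 1 list only, percentile 98.6 of matched random lists).

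Genes of T cell activation and identity were mostly listed in both conditions. All 53 genes of T cell receptor signalling and costimulation had peaks in both lists, including the activation marker Cd69 (5 control and 6 PTC peaks), the co-receptor gene Cd8b1 and the transcription factor gene Jun. With peaks of a fold enrichment of at least 4 alone, 35 of them were listed, 20 in both lists, 10 in control only and 5 in PTC only (42.9% in 1 list only, percentile 99.9 of matched random lists). With all peaks, the 22 listed genes of chemokines, adhesion and migration, the 27 of apoptosis and survival (Mcl1 with 2 peaks in each list) and the 29 of p53 and cell cycle inhibitors (Mdm2 with 3 control and 2 PTC peaks) were also all in both lists; at a fold enrichment of at least 4 these were 9 of 16, 13 of 24 and 17 of 20, within the central 95% of random lists. Of 23 exhaustion genes 21 were in both lists, such as Eomes and Btla, and the inhibitory receptor genes Lag3 (2 peaks, −log10 FDR 12.2) and Cd160 (1 peak, 3.17) were in the control list only. Of 21 cytotoxic genes 19 were in both, among them granzyme B (Gzmb), and Nkg7 (12.2) and Gzma (4.17) were in the control list only. Of the natural killer markers Ncr1 (2.45) and Klra7 (4.19) were in control only and Fcgr3 (7.95) was in PTC only. Of 24 naive and memory genes 23 were in both, such as Foxp1, Klf2 and S1pr1, and Xcl1 was in PTC only (2.39). At a −log10 FDR of at least 5 in both lists the order turned for exhaustion, naive and memory, and natural killer genes. Of 20 listed exhaustion genes 1 was in control only and 3 were in PTC only, and of 23 naive and memory genes 2 and 1. None of 4 natural killer markers was in control only and 2 were in PTC only. For cytotoxic genes the order held, with 4 of 19 in control only and 1 in PTC only (percentile 98.9 for the control-only share).

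Of 34 genes of cytokine signalling 31 were in both lists, and Jak3 (−log10 FDR 5.78), Stat5a (5.14) and Socs7 (4.35) were in control only, a control-only share at percentile 96.8 of random lists matched on strength and 50.8 of those matched on exonic length. Of 23 helper and regulatory T cell genes 17 were in both, including Il2ra and Gata3. Stat3 (12.4) and the interleukin genes Il10, Il13, Il21 and Il22 were in control only, the interleukin genes all with a −log10 FDR below 5. Il13 was named after its values were seen, to complete the 5. At a −log10 FDR of at least 5 in both lists 2 of 18 listed helper and regulatory genes were in control only and 2 in PTC only. Of 33 cell cycle genes 27 were in both lists, such as Myc. The cyclin genes Ccna2 and Ccnb1, Cdk2 and E2f2 were in control only with −log10 FDR from 5.04 to 6.99, and Ccnd1 and Cdk1 were in PTC only with 2.26 and 2.03. At equal list length, where only the control list is cut, 4 were in control only and 5 in PTC only. At a −log10 FDR of at least 5 in both lists 6 of 24 were in control only (percentile 98.5) and none in PTC only. Oas2 of 36 interferon response genes, Pgam1 of 29 nutrient and glycolysis genes, Hmox1 of 28 stress genes, and Tet1 and Hdac7 of 40 chromatin regulators were in control only, with no PTC-only member in these lists. None of these control-only genes reached a −log10 FDR of 5. At a fold enrichment of at least 4 each of these lists had PTC-only members. Control-only and PTC-only genes were then 4 and 4 for interferon, 4 and 2 for nutrients, 4 and 5 for stress and 2 and 1 for chromatin. Of 62 cytosolic ribosomal protein genes 24 had a peak, 4 in control only, 4 in PTC only and 16 in both. For 0 of the 21 gene lists with a member listed did the share of members in 1 list only lie outside the central 95% of random lists matched on peak strength. By chance 1.05 would at most, since a low share can hardly fall outside where random lists often hold no such member. At 0%, the apoptosis and p53 genes still lay at percentiles 4.5 and 3.4. Matched on exonic length instead, 7 of the 21 gene lists lay outside, 6 with a smaller share in 1 list only than the random lists and the erythroid and platelet markers with a larger one.

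**Figure D1:**
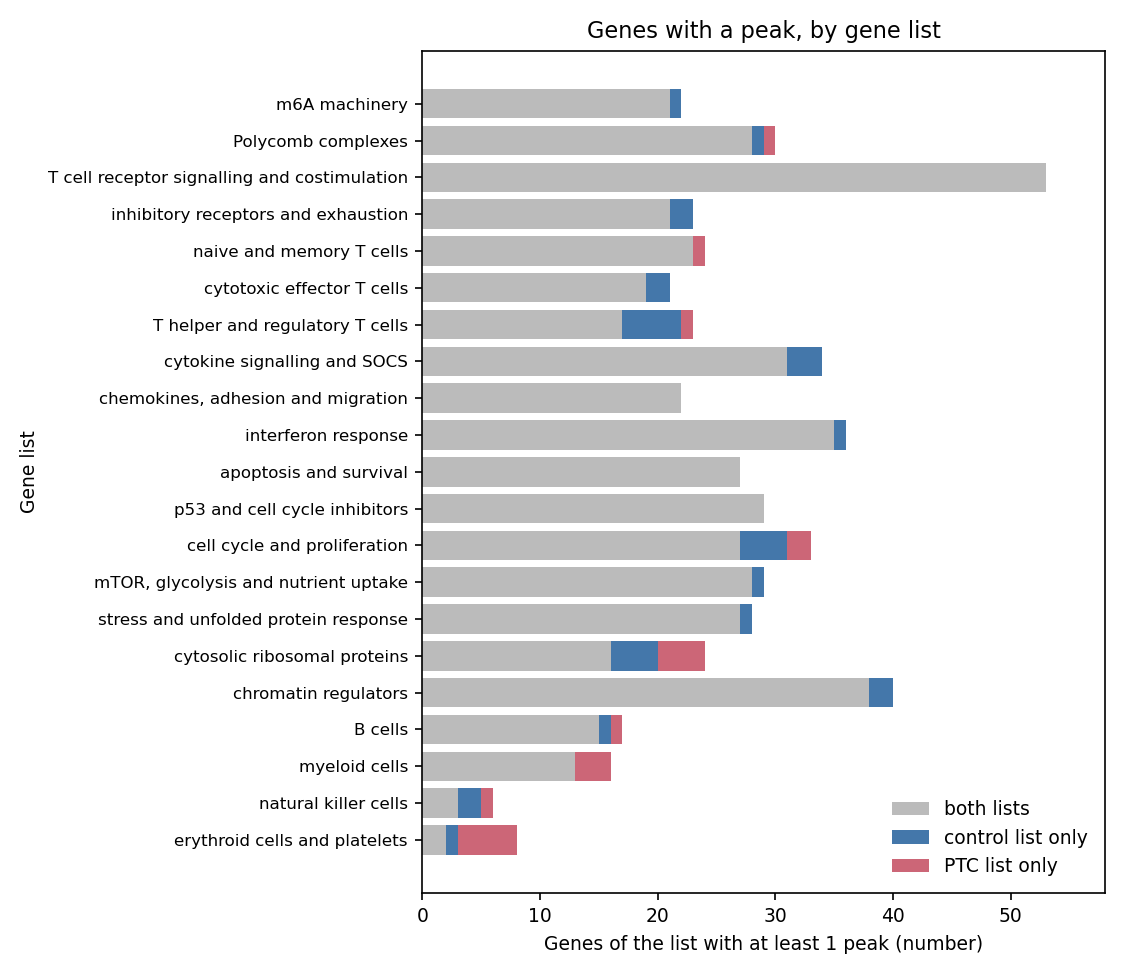
Number of genes of each gene list with at least 1 peak (horizontal axis), split into genes with peaks in both peak lists (grey), in the control list only (blue) and in the PTC list only (red); hepatocyte markers had no peak and are not drawn. All 53 T cell receptor signalling genes had peaks in both lists, and erythroid markers held 5 genes in the PTC list only.

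Markers of other blood cells were also listed. Of 20 B cell markers 17 had a peak and 15 were in both lists, among them Cd79b, Ms4a1, Ighm and Igkc, with Pou2af1 in control only and Cr2 in PTC only. Of 24 myeloid markers 16 had a peak, 13 in both lists (Mpeg1, S100a8, Cd14 and Cebpb) and 3 in PTC only, Tyrobp (−log10 FDR 11.4), Fcgr3 (7.95) and Csf3r (6.54), a PTC-only share at percentile 99.1 of random lists matched on strength and 84.1 of those matched on exonic length. At a fold enrichment of at least 4 the order turned, with 4 of 12 listed myeloid markers in control only and 1 in PTC only, while of 8 listed B cell markers 1 was in control only and 4 were in PTC only. At a −log10 FDR of at least 5 in both lists the myeloid order held, with 4 of 14 in PTC only (percentile 98.5) and none in control only. At equal list length 4 of 16 were in PTC only (99.3) and none in control only. Of 15 erythroid and platelet markers 8 had a peak: 5 in PTC only, among them Hbb-bs, Hbb-bt, Klf1 and Pf4 (PTC-only share at percentile 99.7, and 97.1 at equal list length; Hbb-bs named after its values were seen), Slc4a1 in control only, and Car2 and Alas2 in both. None of the PTC-only erythroid and platelet markers reached a −log10 FDR of 5, and with that threshold on both lists 1 of 3 was in PTC only, its control peaks being weaker (percentile 63.9). Of 14 natural killer markers 6 had a peak, 3 of them in both lists. None of 16 hepatocyte markers had a peak. Among immunoglobulin V segments, 58 of 135 with a peak were in control only, 11 in PTC only and 66 in both.

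Genes with peaks in the control list only numbered 1554, genes in the PTC list only 1023 and genes in both 9836. The 12 strongest control-only genes were led by Ptbp1, a regulator of splicing, with 3 peaks (strongest in the 3' UTR, chromosome 10, 79863901 to 79864141, fold enrichment 1.58, −log10 FDR 48.2), and Ech1, an enzyme of fatty acid oxidation, with 1 peak in coding sequence (chromosome 7, 28825306 to 28826093, 5.86, 35.2). They further held the transcription factor gene Atf5 (25), the formin gene Fmnl1 (24.5), the fatty acid desaturase gene Scd2 (24.2), the mitochondrial carrier gene Ucp2 (24.0), the complex I gene Ndufa9 (22.9), Parp1, which encodes a poly(ADP-ribose) polymerase (21.4), the antisense gene Cdk19os (19.9) and 3 immunoglobulin V segments with values from 19.3 (Iglv2) to 28.1. The 12 strongest PTC-only genes were led by the ribosomal protein gene Rpl41 with a fold enrichment of only 1.21 (chromosome 10, 128548204 to 128548413, 3' UTR, −log10 FDR 66.2), the ribosomal protein gene Rps27rt (65.2) and nucleophosmin, Npm1 (chromosome 11, 33152616 to 33153989, 1.52, 37.2). The others were the translation initiation factor gene Eif3h (26.4), Cops9 (21.8), Pde6h (21.6), the acetyltransferase gene Naa10 (20.9), the histone gene Hist1h2be (20), Cyb5a (19.0), the ferritin gene Fth1 (16.0), Ypel3 (15.1) and Gmppa (14.8). No peak of these 24 genes was overlapped by a peak of the other list. Reads of ribosomal protein, histone and V segment genes can be shared with near-identical copies, so their assignment is uncertain.

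Of the control-only genes 60.4% were protein coding, of the PTC-only genes 63.0% and of those in both lists 85.8%. A −log10 FDR of at least 5 was reached by 325 control-only genes (20.9%), 209 PTC-only genes (20.4%) and 8692 genes in both (88.4%). With the lists reduced to equal length, the order of the counts turned, with 884 genes in control only and 1601 in PTC only.

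At the level of positions, 60.2% of control peaks (95% interval 59.6 to 60.7%) were overlapped by a PTC peak and 78.8% of PTC peaks (78.3 to 79.3%) by a control peak. Peaks placed at random in the same genes gave 35.7% and 43.2%. The overlapped share was larger in stronger bins, from 23.6% in the weakest of 10 equal bins of control peaks to 99.3% in the strongest bin, and from 40.8% to 99.7% for PTC peaks. The 11789 control peaks without a PTC partner had a median −log10 FDR of 3.32 and a width of 180 nt, against 10.1 and 390 nt for those with a partner. For the 4953 PTC peaks without a control partner the values were 3.08 and 179 nt, against 9.43 and 331 nt. Among the genes in both lists 521 had no overlapping pair. Requiring midpoints within 100 bp of each other lowered the shares to 38.7% and 49.0%.

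**Figure D2:**
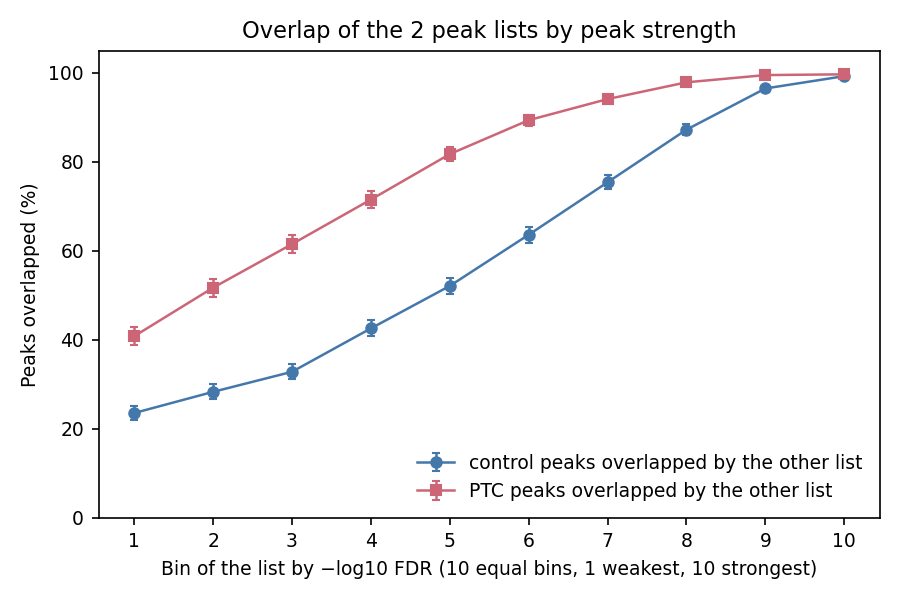
Share of peaks overlapped by the other list (vertical axis, %) for each of 10 equal bins of a list by −log10 FDR (horizontal axis, 1 weakest to 10 strongest); circles are control peaks, squares PTC peaks, and bars exact 95% binomial intervals. The share rises from 23.6% to 99.3% for control and from 40.8% to 99.7% for PTC peaks.

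Both lists had larger shares of peaks in 3' UTRs and near stop codons, where m6A is known to concentrate, than random positions did. In protein-coding genes 45.9% of control and 49.5% of PTC midpoints lay in the 3' UTR, against 36.7% and 36.5% of random positions, 42.2% and 41.0% lay in coding sequence, against 35.4% and 36.4%, 5.93% and 5.79% in the 5' UTR, against 7.31% and 7.63%, and 5.90% and 3.57% in noncoding exons, against 20.6% and 19.5%. The low share in noncoding exons raises the shares of the other regions. The coding sequence values are therefore not read as an excess of their own. The same effect enlarges the gap to random positions in the 3' UTR, and can do so near stop codons. Shares without noncoding exons were not computed, so how much of those gaps belongs to these regions themselves is not known. Within 200 nt of a stop codon lay 18.6% of control midpoints (18.1 to 19.1%) and 23.3% of PTC midpoints, against 13.3% and 13.7% of random positions. Control peaks without a PTC partner lay near a stop codon in 11.1% (10.5 to 11.7%), and PTC peaks without a control partner in 20.2%, while peaks with a partner did so in 23.5% and 24.0%. GGACT was found in 11.6% of control windows (11.2 to 11.95%) and 12.9% of PTC windows (12.5 to 13.4%), against 9.54% and 9.74% at random positions. Without a partner it was found in 9.85% of control and 11.8% of PTC windows. The wider DRACH consensus was in 87.1% and 88.7% of windows against 86.6% and 86.2% at random positions. As random positions lay in noncoding exons more often than peaks, the motif baseline covers partly different sequence, and motif shares without noncoding exons were not computed. Intervals of these shares cover counting error only.

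**Figure D3:**
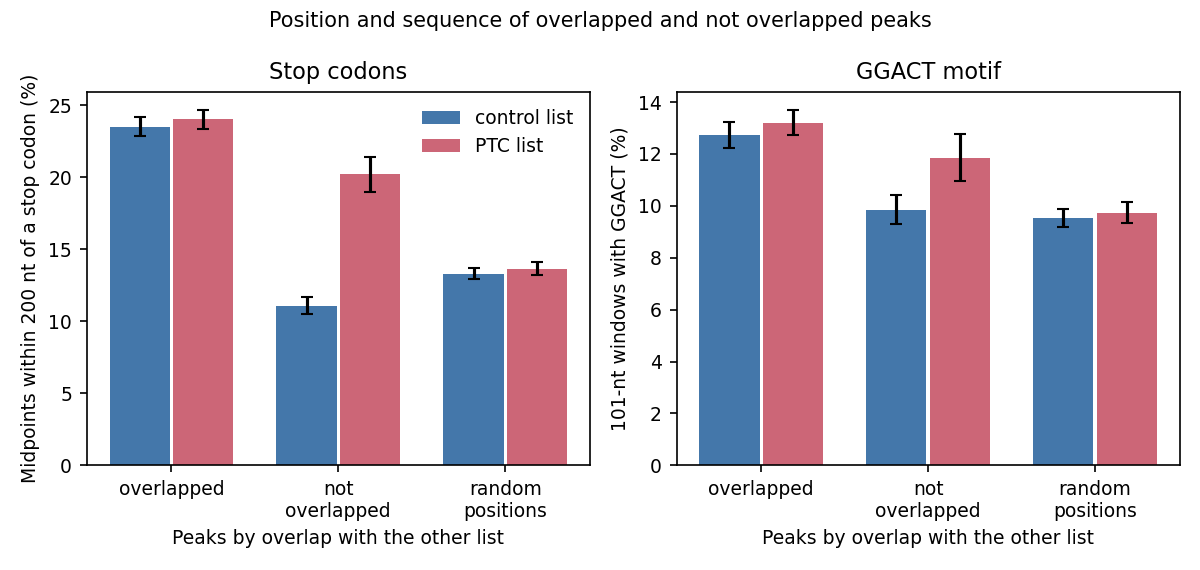
Share of midpoints within 200 nt of a stop codon (left, %) and share of 101-nt windows with GGACT (right, %) for peaks overlapped by the other list, peaks not overlapped and random positions in the same genes; blue bars are the control list, red bars the PTC list, and error bars exact 95% binomial intervals. Not overlapped control peaks reach 11.1% near stop codons and not overlapped PTC peaks 20.2%.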

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

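The alternatives were planned before the data were examined. Of 71 recomputed main values 31 stayed within their interval or within 1.5 times the count, and 40 moved. Of 100 others 60 stayed. The order of the control-only and PTC-only gene counts turned at equal list length, a setting that removes weak peaks from the control list alone. The moved shares of overlapped peaks, control first, were 57.2% and 75.4% with 50% of the shorter peak shared, 44.0% and 55.7% with 50% of each, and 38.7% and 49.0% with midpoints within 100 bp. At a −log10 FDR of at least 5 in both lists the shares were 70.8% and 83.0%, over 15805 control and 13982 PTC peaks, with 982 genes in control only; near a stop codon lay 22.0% and 26.7%, and DRACH was in 87.9% and 89.4%. With that threshold on 1 list and the other kept whole, 82.7% and 93.7% overlapped, 325 and 209 genes were in 1 list only, and 2 gene lists lay outside the central 95% of random lists, those of the cell cycle and myeloid cells. At a fold enrichment of at least 4, 48.6% and 61.2% overlapped over 13327 and 10556 peaks, 5598 genes were in both lists, 24.9% of PTC midpoints lay near a stop codon, DRACH was in 87.9% and 90.1%, and 3 gene lists lay outside, those of T cell receptor signalling, the m6A machinery and B cells. At equal list length 69.2% and 73.1% overlapped, 884 and 1601 genes were in 1 list only, 20.002% of control midpoints lay near a stop codon and 2 gene lists lay outside, those of apoptosis and p53. Fewer peaks enter under these thresholds by construction. Matching random lists on exonic length put 7 gene lists outside, 6 below the range and 1 above; the cause was not tested. Windows of 100 nt on each side held DRACH in 98.1% and 98.6%, and GGACT was in 11.6% and 12.9%. The PTC list had the larger overlapped share under each overlap rule and threshold and at equal list length. Where recomputed, with both thresholds on both lists and at equal list length, it also had the larger share near a stop codon and with DRACH, and the larger motif share with the wider windows and with GGACT. Midpoints stood for summits throughout, so that alternative is the main setting. No paired analysis and no leaving out of a replicate was possible because the lists hold no values per sample. The sample numbers do not say which input belongs to which immunoprecipitate. Depth per sample is unknown, which limits how far absence from a list can be read.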

Other observations

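Apart from Hist1h2be, the genes named in this paragraph and the next were chosen after the peak lists and their values had been seen. So were the gene groups and all groups of V segments, so percentiles of these groups among strength-matched random lists are no test of whether a group stands out. C2H2 zinc finger genes, a large family of DNA-binding factors, were nearly all shared: 490 of 534 had peaks in both lists, 19 in control only and 25 in PTC only, a lower share in 1 list only (8.24%) than in any of the 10000 random lists. Histone genes went the other way, with 22 of 38 in both lists, 5 in control only and 11 in PTC only, the last a share above all random lists. The PTC-only histone genes included Hist1h2be (−log10 FDR 20), Hist1h2ak (13.4) and Hist1h3b (10.3), and the control-only ones Hist1h2af (16.4) and Hist1h2ag (9.87). Among T cell receptor V segments 28 of 53 were in both lists, 11 in control only and 14 in PTC only (percentile 97.8 for the PTC-only share), and at equal list length 6 and 19 of 48 (98.7). Complex I genes had 20 of 29 in both (4 control only, 5 PTC only), mitochondrial ribosomal protein genes 62 of 75 (7 and 6), proteasome genes 29 of 34 (4 and 1) and ubiquitin-specific protease genes 39 of 41 (1 and 1).

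Among the 9836 genes in both lists 4092 (41.6%) held more control peaks, 1574 (16.0%) more PTC peaks and 4170 as many. The glutamine transporter gene Slc38a1 held 19 control and 9 PTC peaks, and Smchd1, a chromatin factor of X inactivation, 13 and 3. In the other direction Vcan, which encodes the matrix proteoglycan versican, held 2 control and 13 PTC peaks, Itgb8 2 and 7, and the receptor tyrosine kinase gene Met 1 and 6. The share near a stop codon went up with strength, from 12.6% in the weakest of 10 equal bins of control peaks to 26.7% in the strongest. For PTC peaks it went from 16.1% in the weakest bin to 30.5% in bin 9, and was 29.1% in the strongest.

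Control peaks without a PTC partner lay near stop codons no more often than random positions, and PTC peaks without a control partner did so more often. The tests of this pattern were chosen after it was seen, and their intervals come from 2000 bootstrap draws of peaks, which are not replicates. Strength as given by the FDR does not account for the whole gap. Averaged over 10 bins of similar −log10 FDR, control peaks with a partner still lay near a stop codon more often by 11.5 percentage points (10.4 to 13.5). Bins counted equally and entered only with at least 20 peaks with and 20 without a partner, and peak width was not matched. At equal list length the peaks without a partner gave 11.3% for control and 20.2% for PTC. At equal FDR a peak with a partner may still be the truer call, so false calls among control peaks without a partner are not excluded. Gene structure argues poorly as the account, since the share of control peaks without a partner was 0.904 times that of random positions in the same genes (0.842 to 0.969), against 1.42 times for PTC peaks without a partner. Whether these control peaks may mark m6A at consensus sites elsewhere stays open, as GGACT exceeded random positions by 0.822 points (0.0271 to 1.56) against 2.96 points for control peaks with a partner. In protein-coding genes, control peaks without a partner lay in noncoding exons more often (11.1% against 2.48%), which this comparison leaves aside. Effects of treatment and of sequencing depth were not tested.

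Immunoglobulin V segments were in control only in 43.0% and in PTC only in 8.15% of 135 genes, and with a −log10 FDR of at least 5 in 31 and 1. The test of B cell markers was chosen after their classes were seen. List length does not account for the direction, since at equal list length 48 were in control only and 12 in PTC only while all genes ran the other way, with 884 and 1601. The control-only share lay at percentile 100 of strength-matched random lists, which is no test, as the group was chosen after its counts were seen. Fewer B cells in the PTC samples may contribute but cannot be told apart here: the control-only share of B cell markers lay at percentile 56.6 and that of plasma cell genes at percentile 65.4, with Ighg1, named after its values were seen, the 1 control-only gene of 12, and presence of a peak is saturated for markers as strong as Cd79b and Igkc, which have peaks in both lists. Different antibody repertoires of the mice and reads shared between V segments were not tested.

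Several of the strongest PTC-only peaks had low fold enrichment; mt-Nd5 (−log10 FDR 207, fold 1.80) and mt-Nd2 (167, fold 1.58), named after their values were seen, were in PTC only. The test of fold was chosen after that was seen. Within the PTC list, PTC-only genes with a −log10 FDR of at least 5 had 0.707 times the fold enrichment (0.654 to 0.788) of shared genes of equal FDR. Control-only genes within the control list gave 0.763 (0.713 to 0.827), so the feature is not one of PTC alone. The ratio restates the pattern and no abundance is known, so small enrichments called in abundant transcripts cannot be told apart from other causes. Pseudogenes made up 25.4% of these PTC-only genes and 16.6% of the control-only ones, a difference of 8.74 percentage points (1.67 to 15.9). Pseudogenes among the strong PTC-only peaks were part of the pattern as first seen, and no sharing of reads was measured. These shares therefore cannot tell whether reads shared with copies add to the peaks. Among all genes pseudogenes were 143 of 1023 in PTC only and 204 of 1554 in control only, with little difference. Whether the peaks mark m6A stays open, as GGACT differed from random positions by -0.543 points (-7.30 to 6.21).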
